A study of Rattus norvegicus with 10 samples.

How the data were processed

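Gene expression in the left ventricle of rats was measured on Affymetrix rat genome expression arrays, 5 after LacZ gene transfer and 5 after transfer of MKK3bE with wild-type p38α, and groups and replicate numbers were taken from the sample titles. The deposited table holds 1 intensity per probe set and array on a linear scale, and the authors made these signals with GCOS 1.2, per the submitters' processing notes. Whether they scaled the arrays to a common target is not given in the sources used here. The values show that they were not brought to one, because the 2% trimmed mean differed 1.481-fold between the highest and lowest array and array medians ran from 60.3 to 88.05. Detection calls were not used here, and the filter described next lay at a signal of about 39.6 units. The fluidics status and module of each array came from the experiment files, per the file headers, and lots and dates in those files were empty or invalid.

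Signals were taken as log2(signal + 16), which understates the change of dim probe sets, and quantile normalized between arrays. The comparison, the gene lists, the rule for named genes and the alternatives, apart from those named at the end, were fixed before the data were examined. That plan was to use the deposited scaling unless the arrays proved unscaled, so quantile normalization became the main setting and the signals as deposited an alternative. The 57 control probe sets were left out, as were the dimmest 40% of the other 31042 by mean log2 value over the 10 arrays, which left 18625. For named genes with a group mean below the limit of that filter (5.797), each array of that group below the limit was set to it, and the change is given as at least that size, a rule set after the values had been seen. Of all 31099 probe sets, controls included, 20832 named 1 gene in the platform annotation, 436 named several and 9831 none. Entrez identifiers of 20764 of the 20832 were found in the RefSeq gene table of the GRCr8 assembly, used for names only, and 68 were not. Genes were named only from probe sets with 1 symbol, and where a gene had several, the one with the highest mean log2 value stood for it. Where another probe set of a named gene passed in the opposite direction, or passed while the chosen one did not, this is stated with the gene. Akap6, Rasd2, Ucp3, Hadha, Cacna1c, Thy1, Kcnj3, Cd8a and Dusp6 passed at the chosen probe set and had at least 1 other tested probe set that did not.

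Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. No covariate was used, since the labels state no pairing. The 29 gene lists came from textbook knowledge. They covered cell cycle phases, cytokines, leukocyte adhesion, interferon response, antigen presentation, immediate early genes, the p38 pathway, hypertrophy, contraction, calcium handling and ion channels, oxidative phosphorylation, fatty acid oxidation, glucose use, matrix, apoptosis, heat shock, oxidative stress, and markers of macrophages, T and NK cells, B cells, neutrophils, mast cells, fibroblasts, endothelium, smooth muscle, red cells, atrium and skeletal muscle. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, over 10596 genes, and 27 lists had at least 3 tested members. Adjusted over lists, 10 were higher and 6 lower, and with an estimated correlation none passed in either direction. At that setting the calls of all 16 lists were lost. Members are counted as passed over all tested probe sets and adjusted over the list alone.

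Named genes followed a fixed rule. They comprise Map2k3 and Mapk14, a fixed set of 12 cardiac, inflammatory and cell cycle genes, the 12 largest rises and 12 largest falls among changed genes with a symbol of their own, and the members of each list with the smallest p, of which some are left out here. Other members are named, with no value, to identify small counts, and these were chosen after their values were seen. The steps were tested on simulated data, in 5 runs with 200 of 18625 probe sets changed between 5 and 5 arrays. There, 38.2% of changes of 0.5 on the log2 scale were recovered, 84.8% of changes of 1 and 99.1% of changes of 2, with 4.92% false calls on average, and a list shift was recovered in all 5 runs. The simulated noise was independent between probe sets, and a smaller share of them changed than in the data. These runs therefore do not show how often probe sets or lists are called falsely where genes vary together.

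Alternatives comprised other pseudocounts, scalings, filters, thresholds and variance models, array weights, replicate number, fluidics status and module as blocks, each array left out in turn, averaging of probe sets, and other list tests. Averaging took all probe sets of a gene, those too dim to be tested included. For Inhba, Fos, Cbln2, Ankrd13d, Zyg11b, Fas and Kdr every added probe set was too dim. Values within each fluidics status were added after the data were seen. Figures were drawn with matplotlib 3.10.9. Array quality was read from the control probe sets. The ratio of 3′ to 5′ β-actin signal was 2.16 ± 0.26 (SD, n = 5) in LacZ and 2.11 ± 0.36 in p38 arrays.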

Results

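The data describe left ventricular tissue of rats 3 days after gene transfer into the heart. One group of 5 samples had received MKK3bE, a constitutively active form of the kinase that activates p38, together with wild-type p38α mitogen-activated protein kinase, and is called p38 here. The control group of 5 samples had received LacZ, the bacterial β-galactosidase gene. The rats weighed 250 to 300 g, and the labels describe 9 of the 10 as male Sprague-Dawley rats. Total RNA of each sample was hybridised to 1 short-oligonucleotide array, and 18625 of 31042 probe sets were bright enough to be tested. The labels do not say in so many words that each array came from a different animal, so p-values measure the spread between these samples. The number of arrays, 5 per group, limits the precision of every value, and the median 95% interval of a log2 fold change reached 0.28 to either side. Errors of log2 fold changes are standard errors of the limma fit over 5 arrays per group, and adjusted p refers to that fit with Benjamini-Hochberg adjustment.

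The question of the comparison was which ventricular transcripts differ 3 days after p38 activation. In p38 hearts, 20 of 26 tested genes of mitosis, 7 of 18 cytokines and chemokines, 14 of 17 macrophage markers, 11 of 18 immediate early genes and both natriuretic peptide genes rose, while 14 of 23 fatty acid oxidation genes, 7 of 18 genes of calcium handling and ion channels and 2 of 3 erythroid markers fell. Camera with a preset correlation shifted each of these 7 lists, and each had an adjusted p = 0.270 with an estimated correlation. With 1 array left out these 7 counts were as low as 16, 6, 7, 7, 8, 2 and 1, and the arrays are named with the lists below. With the signals as deposited, without normalization between arrays, they were 19, 6, 9, 9, 2, 0 and 1, so most of these falls depended on such normalization. With other normalizations the falls in the fatty acid oxidation, calcium handling and erythroid lists were 16, 7 and 2 (cyclic loess) and 11, 5 and 2 (median centring). The gene with the largest rise was Inhba, which encodes the activin βA subunit, at 9.94-fold (log2 fold change 3.31 ± 0.41, adjusted p = 0.00498). Its rise was 4.76-fold when all its probe sets were averaged, the others being too dim to be tested. The matricellular protein gene Spp1 (osteopontin) rose 7.14-fold, and the stress-induced transcription factor Atf3 rose 6.36-fold with the smallest adjusted p of these, 0.00344. The largest fall belonged to Acacb, the mitochondria-associated acetyl-CoA carboxylase whose product restrains fatty acid uptake into mitochondria, with a log2 fold change of -1.19 ± 0.23 (adjusted p = 0.0107). For Inhba, Spp1 and Atf3, each of the 5 p38 arrays lay above all 5 LacZ arrays, and for Acacb 4 of the 5 p38 arrays lay below them.

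**Figure D1:**
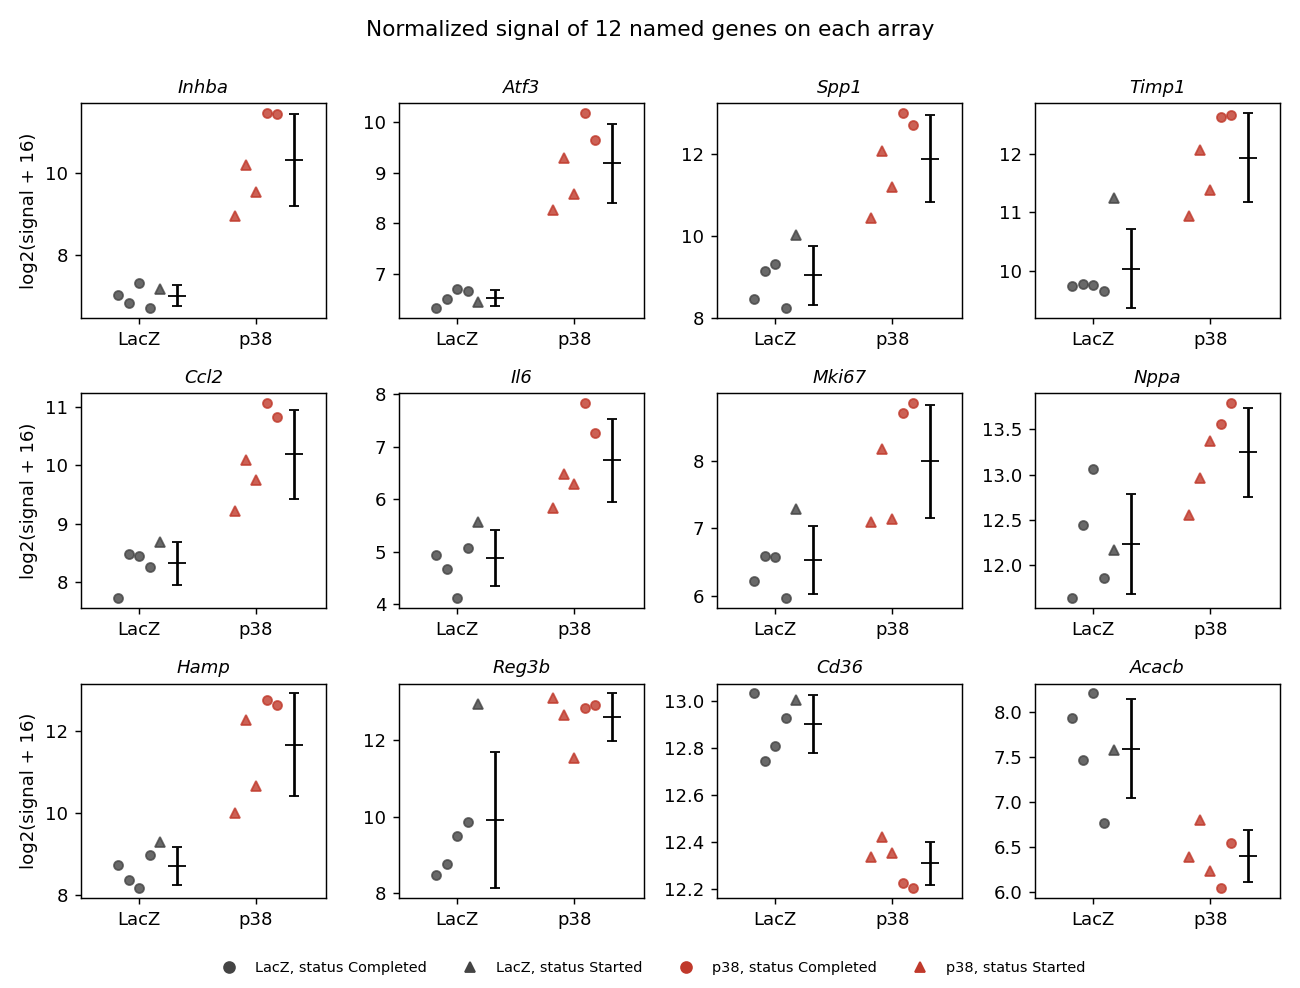
Normalized log2(signal + 16) of 12 named genes on each of the 10 arrays, LacZ in grey and p38 in red, with circles and triangles for fluidics status Completed and Started, and a bar for the mean and SD of 5 arrays. All 5 p38 arrays lie above the LacZ arrays for Inhba, Atf3, Spp1, Ccl2, Il6 and Hamp and below them for Cd36, while for Reg3b LacZ 5 reaches the p38 arrays.

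Over all tested probe sets, 1601 rose and 1378 fell in p38, together 15.99% of the 18625 tested. Rises were the larger changes, since 232 probe sets rose and 13 fell by at least 2-fold. With 1 probe set per gene, 1227 of 10596 named genes rose and 660 fell, and 571 of the changed probe sets carried no gene name of their own. The groups did not overlap for 2057 probe sets, or 11.04%, where chance gives 0.794%. The balance of rises and falls depended on scaling. With the signals as deposited, where the median log2 fold change of the tested probe sets was 0.11 against -0.03 after quantile normalization, 956 of the same 18625 probe sets rose and 87 fell, so that 91.66% of the changed ones were higher, against 53.74% in the main setting. Camera put 10 gene lists higher and 6 lower, but 11 of 100 splits of the 10 arrays into 5 and 5, the real one included, shifted as many lists. For a single list, as small a p occurred in 1 to 18 of the splits for 15 of the 16 lists, and in 54 for extracellular matrix. The other splits kept some of the group difference, so these counts do not measure chance alone. The counts also moved by over 1.5 times when single arrays were left out. They were 847 higher and 659 lower without LacZ 1, 923 and 707 without LacZ 2, 750 and 536 without LacZ 3, 989 and 842 without LacZ 4, 913 and 765 without p38 2, 693 and 540 without p38 4, 965 and 767 without p38 5, and 2316 and 2149 without p38 1.

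The rat probe sets for the delivered kinases did not pass the test. Map2k3, the gene of MKK3, had a log2 fold change of 0.11 ± 0.07 (adjusted p = 0.329) and Mapk14, the gene of p38α, one of -0.03 ± 0.07 (adjusted p = 0.836). These probe sets need not measure the delivered cDNA, so the values check neither its presence nor its absence. Among 20 tested pathway components and dual-specificity phosphatases, 4 rose, namely Dusp5, Dusp6, Rps6ka4 and Gadd45a, Mknk2 fell, and 15 did not pass. Adjusted over the list alone, 5 rose and 2 fell. Without any 1 of LacZ 1 to 4, p38 2, p38 4 and p38 5 the number of rises was 1, and without LacZ 5 it was 2. The fall of Mknk2 was lost without LacZ 1, LacZ 2, LacZ 3, LacZ 5, p38 2, p38 4 or p38 5 (adjusted p from 0.0535 to 0.0704) with the signals as deposited (adjusted p = 0.622), with median centring (0.104) and with the fluidics module as a block (0.0697). The rise of Dusp5 was lost without LacZ 1 (adjusted p = 0.0508) and with the fluidics module as a block (0.0506), and that of Dusp6 without LacZ 2, LacZ 3, LacZ 4, p38 2, p38 4 or p38 5 (adjusted p from 0.0663 to 0.0916), with the signals as deposited (0.0559) and without a variance trend (0.0520). The list as a whole was not shifted (camera adjusted p = 0.819). Its median of -0.08 and mean of 0.04 differed in sign, and the median was 0.09 with the signals as deposited.

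Of 26 tested genes of mitosis and the G2/M phase, 20 rose and 6 did not pass, and 25 rose when adjusted over the list alone. Cyclin A2 (Ccna2) rose at least 3.07-fold (adjusted p = 0.00858), Ccnb2 2.89-fold, the proliferation antigen gene Mki67 2.77-fold (adjusted p = 0.0179) and topoisomerase IIα (Top2a) 2.54-fold (adjusted p = 0.0119). The brightest probe set of Ccnb1 did not pass (log2 fold change 0.78 ± 0.27, adjusted p = 0.0602), although its other probe set rose. Among 26 genes of the G1/S transition and DNA replication, 12 rose, or 17 adjusted over the list alone, including the helicase subunit Mcm6 at 2.58-fold, and none fell. The 12 became 4 without LacZ 1, LacZ 3, p38 2 or p38 4, 5 without LacZ 2 or p38 5 and 7 without LacZ 4. The median log2 fold change was 1.28 for the mitosis list (camera adjusted p = 1.488e-12, but adjusted p = 0.270 with an estimated correlation) and 0.46 for the replication list (adjusted p = 2.232e-07, and 0.270 as adjusted p with an estimated correlation). Mean levels of the mitosis list were also raised on LacZ 5, by 0.68 against values of -0.30 to -0.10 on the other LacZ arrays.

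The monocyte-attracting chemokines Ccl7 and Ccl2 rose 4.44-fold (log2 fold change 2.15 ± 0.34) and 3.68-fold (1.88 ± 0.30, adjusted p = 0.00732), and the cytokine Il6 rose at least 1.92-fold (adjusted p = 0.00993). Of 18 tested cytokines and chemokines, 7 rose, the others being Il1b, Il18, Il33 and Cxcl16, and 9 rose adjusted over the list alone. Leukocyte adhesion genes gave 4 rises among 9 tested, 5 adjusted over the list alone, with E-selectin (Sele) at least 2.02-fold and Icam1 1.66-fold higher, and 2 rises without LacZ 1, LacZ 2, LacZ 3, p38 2, p38 4 or p38 5. Antigen processing and presentation gave 5 of 16, or 8 over the list alone, with the immunoproteasome subunit Psmb8 at 1.72-fold, and 8 without p38 1. Of 17 macrophage and monocyte markers 14 rose, 15 adjusted over the list alone, among them the inhibitory Fc receptor Fcgr2b at 2.75-fold, Lgals3 (galectin-3) at 2.50-fold and lysozyme (Lyz2) at 1.51-fold. The 14 became 7 without LacZ 3 or p38 4, 8 without LacZ 1 or p38 2 and 9 without LacZ 2, LacZ 4 or p38 5. Camera adjusted p-values of these 4 lists were 0.00117, 0.00332, 9.524e-05 and 2.232e-07, and each list had an adjusted p = 0.270 with an estimated correlation. The mean of the macrophage list was also raised on LacZ 5, by 0.37 against values of -0.15 to -0.01 on the other LacZ arrays.

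Camera did not shift the lists of interferon response genes, T and NK cell markers and neutrophil markers. By limma, none of 19 tested interferon response genes passed over all probe sets or adjusted over the list alone, while 5 had an unadjusted p under 0.05 (camera adjusted p of the list 0.207). Psmb10 came nearest at a log2 fold change of 0.37 ± 0.12 (adjusted p = 0.0512). Psmb10 passed in 8 of 22 other settings, for example with fluidics status as a block (adjusted p = 0.0233), and 2 of the 19 rose with median centring or without LacZ 5, and 4 without p38 3. The list was higher in 1 of 25 other settings, without LacZ 3 (adjusted p = 0.0409), and within Completed arrays (0.0437). Among 13 T and NK cell markers only Cd8a passed in the main setting, and none did adjusted over the list alone (list adjusted p = 0.112). The call of Cd8a was lost without any 1 of LacZ 1 to 5, p38 4 and p38 5 (adjusted p from 0.0513 to 0.0785), with the fluidics module as a block (0.0516) and when its probe sets were averaged (0.0519). Of 3 neutrophil markers tested, Lcn2 (lipocalin-2) rose 2.87-fold (adjusted p = 0.0349), but not with fluidics status as a block (adjusted p = 0.0683) or without LacZ 1, LacZ 2, LacZ 3, LacZ 4, p38 2 or p38 4 (adjusted p from 0.0761 to 0.0908). It was also lost with a robust variance model (adjusted p = 0.0683) and without a variance trend (0.0519). Adjusted over the list alone 2 rose, and the list was not shifted (adjusted p = 0.0860). Among 4 mast cell markers the chymase Cma1 fell, and 2 fell adjusted over the list alone (camera adjusted p = 0.0298, adjusted p = 0.290 with an estimated correlation). The list's call was also lost without p38 3 (adjusted p = 0.0674) and with array weights (0.103). The call of Cma1 was lost without LacZ 1, LacZ 2, LacZ 3, LacZ 4, p38 2, p38 4 or p38 5 (adjusted p from 0.0524 to 0.101) and with the signals as deposited (0.113). B cell markers had 2 tested members, neither of which passed.

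Of 18 tested immediate early genes 11 rose, 7 without LacZ 1 or LacZ 3, and 12 adjusted over the list alone, with Atf3 followed by Fos at 3.61-fold (1.69-fold when its probe sets were averaged) and Egr2 at 2.21-fold, and none fell (camera adjusted p = 1.305e-05, adjusted p = 0.270 with an estimated correlation). In the fetal and hypertrophic list 6 of 11 rose, 3 without LacZ 1, LacZ 3 or p38 5 and 2 without p38 4, and 6 adjusted over the list alone (camera adjusted p = 0.000470, and an adjusted p = 0.270 with an estimated correlation). The connective tissue growth factor gene Ccn2 rose 2.72-fold, the B-type natriuretic peptide gene Nppb 1.59-fold (log2 fold change 0.67 ± 0.15, adjusted p = 0.0158) and the atrial natriuretic peptide gene Nppa 2.02-fold (1.01 ± 0.26, adjusted p = 0.0236). The Nppa call was lost in some settings, as its adjusted p was 0.0588 without LacZ 1, 0.0559 without LacZ 4, 0.0632 without p38 4 and 0.0526 without p38 5, and 0.0551 with the fluidics module as a block. Its log2 fold change stayed between 0.86 and 1.22 in all other settings run. The fetal myosin gene Myh7 had a log2 fold change of 0.11 ± 0.07 (adjusted p = 0.295). Among 15 heat shock and unfolded protein genes Hspb1 (1.89-fold) and Atf4 rose while Hspd1, Herpud1 and Bag3 fell. Adjusted over the list alone 3 rose and 3 fell, and the list was not shifted (adjusted p = 0.156). With any 1 array other than p38 3 left out 1 fell, and without p38 1 7 rose. The call of Atf4 was lost without LacZ 2, LacZ 3, LacZ 4, p38 2, p38 4 or p38 5 (adjusted p from 0.0540 to 0.0680) and with the signals as deposited (0.0513), and that of Hspd1 with the signals as deposited (adjusted p = 0.348).

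**Figure D2:**
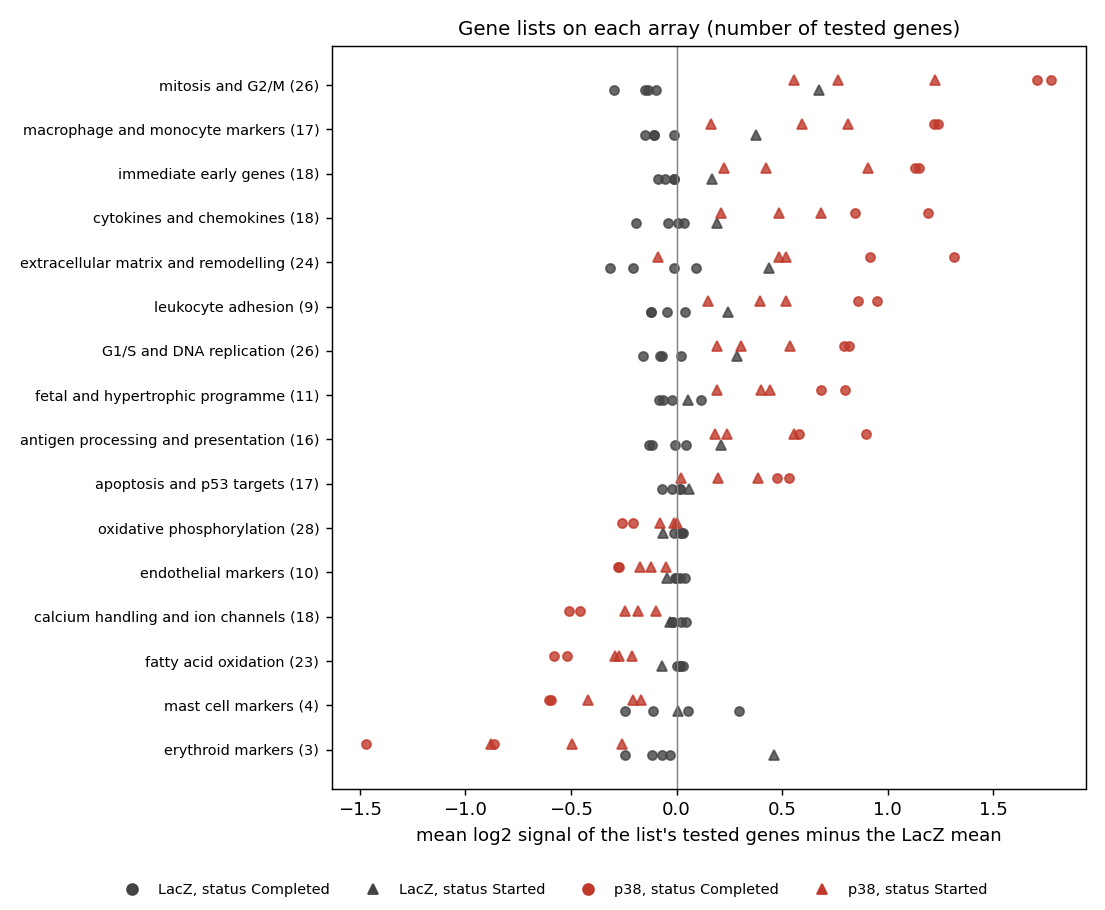
Mean log2 signal of the tested genes of the 16 shifted lists on each array, as the difference from the mean of the 5 LacZ arrays, LacZ in grey and p38 in red, with circles and triangles for fluidics status Completed and Started. For mitosis and G2/M the p38 arrays span 0.56 to 1.77, and LacZ 5 stands at 0.68.

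Further genes were among the 12 largest rises. Hamp, which encodes the iron hormone hepcidin, rose 7.70-fold (log2 fold change 2.95 ± 0.47), Cbln2 (cerebellin 2) at least 2.76-fold, its place among the 12 resting on LacZ signals below the brightness limit, the decoy receptor Tnfrsf11b (osteoprotegerin) 4.26-fold, and the cholesterol 25-hydroxylase gene Ch25h 3.93-fold. Timp1, an inhibitor of matrix metalloproteinases, rose 3.76-fold (1.91 ± 0.36, adjusted p = 0.00977). The lectin gene Reg3b rose 6.51-fold (2.70 ± 0.66, adjusted p = 0.0198), but LacZ 5 stood at 12.96 beside p38 values of 11.53 to 13.10. Without LacZ 5 Reg3b rose 11.04-fold, and the adjusted p was 0.0509 without LacZ 1 and 0.0542 without LacZ 3, and 0.0557 with a robust variance model. Of 24 extracellular matrix genes 5 rose, Spp1, Timp1, Tnc, Mmp12 and Col8a1, or 7 adjusted over the list alone, while 19 did not pass. The 5 became 3 without any 1 of LacZ 1 to 4, p38 2, p38 4 and p38 5, and 13 without p38 1. The list's camera adjusted p of 0.00164 became an adjusted p = 0.552 with an estimated correlation. As small a p for this list occurred in 54 of 100 splits of the arrays, and within Started arrays camera called the list lower (median -0.23, adjusted p = 0.00499), where LacZ 5 is the only LacZ array. Among 17 genes of apoptosis and p53 targets, 5 rose, 3 without LacZ 3 or p38 4, and 5 adjusted over the list alone, with the cell cycle inhibitor gene Cdkn1a at 1.67-fold (2.56-fold when its probe sets were averaged) and the death receptor gene Fas at 1.49-fold (camera adjusted p = 0.00270, adjusted p = 0.290 with an estimated correlation). Fas did not pass when its probe sets were averaged (adjusted p = 0.338). In the oxidative stress list the sulfiredoxin gene Srxn1 rose 2.57-fold (0.68 on the log2 scale when its probe sets were averaged) and Gclc rose, Sod3, Cat and Ucp2 fell, or 5 rose and 3 fell adjusted over the list alone. The list had 1 rise without any 1 of LacZ 1 to 4, p38 2, p38 4 and p38 5, and 4 without p38 1. Sod3 and Cat did not pass with the signals as deposited (adjusted p = 0.0974 and 0.298). The list was not shifted (adjusted p = 0.985, with a positive mean and median against a negative direction in the test).

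Of 23 tested genes of fatty acid oxidation, 14 fell and 9 did not pass, none rose, and 19 fell adjusted over the list alone. Without LacZ 3, 8 fell. The list median was -0.37 (camera adjusted p = 4.41e-11, adjusted p = 0.270 with an estimated correlation). The fatty acid transporter gene Cd36 fell by 0.59 on the log2 scale (SE 0.07, adjusted p = 0.00396), Cpt1b, the rate-limiting carnitine palmitoyltransferase of muscle, by 0.51 (adjusted p = 0.00732) and Hadha, a subunit of the mitochondrial trifunctional protein, by 0.42. The uncoupling protein gene Ucp3 fell by 0.91 (adjusted p = 0.0227), a call lost without LacZ 1, LacZ 2 or LacZ 3 (adjusted p = 0.0587, 0.0579 and 0.0516), with the fluidics module as a block (0.0572) and with the signals as deposited (0.0511). The mean of the list stood at -0.068 on LacZ 5, below the other LacZ arrays. Of 28 oxidative phosphorylation genes Ndufs1, Ndufv1 and Sdha fell, also 3 adjusted over the list alone, 9 without p38 1 and 7 without p38 3, while 25 did not pass, with a median of -0.12 (adjusted p = 3.652e-05, adjusted p = 0.390 with an estimated correlation). With the signals as deposited, 2 of the fatty acid oxidation genes and none of the oxidative phosphorylation genes fell, with medians of -0.21 and -0.08 where all tested probe sets had a median of 0.11. There Hadha had an adjusted p = 0.0681. The call of Sdha was also lost without LacZ 1 (adjusted p = 0.0602) or LacZ 2 (0.0572), and without a variance trend (0.0761). In the glucose list Slc2a4 (the insulin-responsive transporter GLUT4), Hk2 and Pfkm fell and Pfkp rose 1.95-fold, and 16 of 20 did not pass (list adjusted p = 0.0548). The glucose list was not called in the main setting, but was called lower in 11 of 25 others, for example with fry (adjusted p = 0.0107), with the signals as deposited (0.00415) and with median centring (0.00793), and with an estimated correlation its adjusted p = 0.270. Adjusted over the list alone 1 rose and 6 fell. It had 1 fall without LacZ 3, 5 without p38 1 and 6 without p38 3, where 2 rose. None of the falls was kept with the signals as deposited, and that of Slc2a4 was lost without LacZ 3 (adjusted p = 0.0541).

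Of 18 tested genes of calcium handling and ion channels 7 fell, also adjusted over the list alone, and none rose. The 7 became 2 without LacZ 3 or p38 4, 3 without LacZ 1, LacZ 2 or p38 5 and 4 without p38 2. Kcnip2, a subunit of the transient outward current, fell by 0.49 (adjusted p = 0.0164), and the L-type calcium channel gene Cacna1c by 0.44 (list camera adjusted p = 5.371e-05, adjusted p = 0.270 with an estimated correlation). None of the 18 passed with the signals as deposited, and Kcnip2 did not pass when its probe sets were averaged (adjusted p = 0.0897). The calcium pump gene Atp2a2 had a log2 fold change of -0.07 ± 0.03 (adjusted p = 0.169), although another probe set of it fell. Of 17 contractile genes Ldb3, Actn2 and Mybpc3 fell, Csrp3 rose and 13 did not pass (list adjusted p = 0.229). The list was called lower in 4 of 25 other settings, with the signals as deposited (adjusted p = 0.000282), cyclic loess (0.00214), median centring (5.946e-05) and fry (0.0193). Adjusted over the list alone 1 rose and 4 fell, and none of the 17 passed with the signals as deposited. The rise of Csrp3 was also lost with cyclic loess, with median centring, and without LacZ 3, p38 2, p38 4 or p38 5 (adjusted p from 0.0503 to 0.0620 without 1 array). Without a variance trend neither Csrp3 (adjusted p = 0.0758) nor Actn2 (0.0639) passed. The adult myosin gene Myh6 had a log2 fold change of 0.04 ± 0.04 (adjusted p = 0.558) at its brightest probe set, and a second probe set fell, as did their mean (log2 fold change -0.34, adjusted p = 0.0176). Contractile genes were very bright, 16 of the 17 having a LacZ mean log2 signal over 13, a range in which the fatty acid oxidation genes also had small fold changes (median -0.13 over 5 genes, against -0.40 over the 18 dimmer ones).

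**Figure D3:**
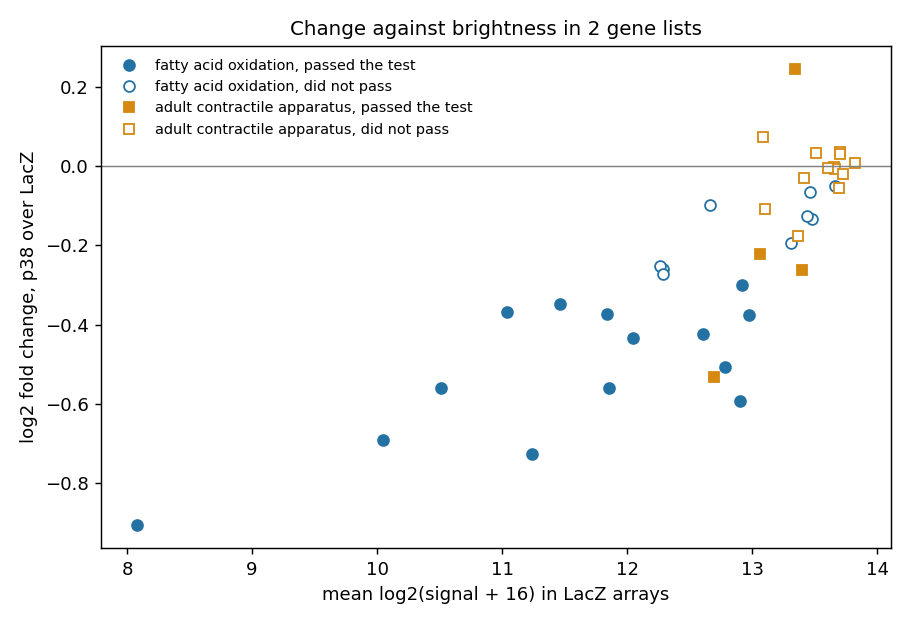
Log2 fold change of p38 over LacZ against mean log2(signal + 16) in LacZ arrays for 23 fatty acid oxidation genes (circles) and 17 contractile genes (squares), filled where the adjusted p passed. Fold changes lie near 0 among the brightest genes of both lists, and 16 of the 17 contractile genes lie above 13.

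The remaining large falls did not share a list. Akap6, which anchors protein kinase A at the cardiomyocyte's nuclear envelope, fell by 1.07 on the log2 scale (SE 0.14, adjusted p = 0.00498). Ankrd13d fell by 1.14 (0.52 when its probe sets were averaged), the GTPase gene Rasd2 by 0.92, Zyg11b by 0.88, the cardiac growth factor gene Fgf16 by 0.84, Ky by 0.83 and the deubiquitinase gene Usp2 by 0.81. The fall of Zyg11b was lost when all its probe sets were averaged (adjusted p = 0.0897). Ppl (periplakin) fell by at least 0.49 (adjusted p = 0.0311), and its adjusted p was 0.0628 without LacZ 2, 0.0639 without LacZ 3, 0.0714 without LacZ 4, 0.0702 without p38 2, 0.0836 without p38 4 and 0.0693 without p38 5.

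The haemoglobin gene Hba-a3 fell by 1.01 (adjusted p = 0.0187, or 0.0533 with the signals as deposited) and Slc4a1, the band 3 anion exchanger of red cells, by 1.01 (adjusted p = 0.0163). Of 3 tested erythroid markers Slc4a1 and Hbb fell, or 3 adjusted over the list alone (camera adjusted p = 0.00893, adjusted p = 0.270 with an estimated correlation). The call of Hbb was lost without p38 4 (adjusted p = 0.0522), with the fluidics module as a block (0.0530) and with the signals as deposited (0.0760), and 3 fell without p38 1. Of 10 endothelial markers Tie1 and Kdr fell, also 2 adjusted over the list alone, with a median of -0.14 (adjusted p = 0.0206, adjusted p = 0.270 with an estimated correlation), and neither fell with the signals as deposited, where the median turned to 0.03. The call of Kdr was also lost without LacZ 1, LacZ 3, LacZ 4, p38 2, p38 4 or p38 5 (adjusted p from 0.0540 to 0.0938), with cyclic loess (0.0582), median centring (0.102), the fluidics module as a block (0.0819) and no variance trend (0.0704), and when its probe sets were averaged (0.171). Among 9 smooth muscle and pericyte markers calponin (Cnn1, 3.75-fold) and Tagln rose while Myh11 and Smtn fell, also adjusted over the list alone, the list's mean being positive and its median of -0.18 negative (adjusted p = 0.531). The call of Tagln was lost without LacZ 1, LacZ 3, LacZ 4, p38 2 or p38 4 (adjusted p from 0.0533 to 0.0640), with the fluidics module as a block (0.0530) and with the signals as deposited (0.0509). The list had no fall without LacZ 1, LacZ 2, LacZ 3, p38 2, p38 4 or p38 5, and 1 without LacZ 4. The call of Smtn was lost without LacZ 1, LacZ 2, LacZ 3, p38 2, p38 4 or p38 5 (adjusted p from 0.0611 to 0.0686) and with the signals as deposited (0.143). Of 11 fibroblast markers Thy1 and S100a4, which leukocytes also express, rose 2.11-fold and 2.62-fold, and 3 rose adjusted over the list alone (list adjusted p = 0.531). Its mean was positive, while its median of -0.03 was 0.09 with the signals as deposited and 0.01 with cyclic loess. Among 6 atrial markers Kcnj3 fell, also adjusted over the list alone (list adjusted p = 0.531, with a mean and a median above 0 against a negative direction in the test), and neither of 2 tested skeletal muscle markers passed.

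Arrays of the 2 groups also differed in a fluidics status recorded for each array, which was Completed for LacZ 1 to 4, p38 4 and p38 5 and Started for LacZ 5 and p38 1 to 3. With this status as a block, 1944 probe sets rose and 1955 fell, and 10 lists were higher and 6 lower. Within the Completed arrays (4 LacZ, 2 p38) 2919 rose and 3364 fell, and within the Started arrays (1 LacZ, 3 p38) 3 rose and 2 fell. All Started values rest on LacZ 5 as the only LacZ array, which is assumed to vary like the others. Inhba had log2 fold changes of 4.49 and 2.38 within Completed and Started arrays, Atf3 3.37 and 2.28, Ccl2 2.72 and 1.01, and Cd36 -0.66 and -0.63. Mki67 had 2.45 and 0.18, Timp1 2.93 and 0.22, Reg3b 3.74 and -0.53, and Ucp3 -1.29 and 0.01. Of 87 named genes past the threshold in the main setting, which includes these arrays, 84 had the same direction within Started arrays. Camera put 12 lists higher and 5 lower within Completed arrays and 4 higher and 5 lower within Started arrays. The Started medians of the mitosis, macrophage and extracellular matrix lists, 0.16, 0.12 and -0.23, were taken against the raised means of LacZ 5 in these lists (0.68, 0.37 and 0.44). The glucose list was also lower within Started arrays (adjusted p = 0.0351), but not within Completed arrays (adjusted p = 0.131).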

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

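Except for the counts over other splits of the arrays, all tests of explanations in this part were chosen after the results they concern had been seen. Some conditions were also set only once a value was known. The rule written for the fatty acid comparison at the lower of its brightness bounds was met as it stood, and the demand that both gene classes be alike in brightness came afterwards. So did the demand for at least 6 p38 arrays in the tests of RNA integrity and brightness on the first principal component, which left both open where the rules as written had counted against them. So did the brightness limit for the comparison at 13 and above, which was only just met and did not alter its outcome. The limit of 0.05 for listing spike-in differences also came afterwards, and it left out the poly-A spike-ins (0.42 higher in p38 on the log2 scale, exact permutation p = 0.0794). In 280 sets of 5 arrays (named genes, lists and array measures), 21 held an array far from the other 4 by Dixon's ratio with a critical value of 0.71, where chance gives about 1 in 20, and 11 of the 21 concerned LacZ 5.

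LacZ 5 lay above the other LacZ arrays for Timp1 (11.25 against 9.66 to 9.77), Top2a (7.34 against 6.08 to 6.45), Fos (7.63 against 6.65 to 6.92), Ccn2 (10.93 against 9.96 to 10.20), Lcn2 (11.13 against 8.96 to 9.08), Vim (12.73 against 12.27 to 12.39) and Alas2 (9.95 against 8.70 to 8.99). It was also apart in the mean of the mitosis list (0.68), of the macrophage list (0.37 against -0.15 to -0.01) and of the fatty acid oxidation list (-0.068 against 0.004 to 0.033), and on the first principal component of the tested probe sets (-8.12 against -26.60 to -24.54). Among other LacZ arrays, LacZ 4 was high in Cma1 (7.71), LacZ 1 low in Ldb3 (12.56) and in the contractile list (-0.021), and LacZ 3 high in Atp2a2 (13.91). The step in Atp2a2 was small. It was flagged because quantile normalization, which gives equal ranks equal values, set every other LacZ array to 13.876. Among p38 arrays, p38 3 was low in Reg3b (11.53) and Zyg11b (6.47) and high in Mknk2 (10.45), p38 4 low in Hba-a3 (9.22) and Myh6 (13.68), and p38 5 low in Ucp3 (6.50).

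The p38 arrays were spread widely along the first principal component, which held 48.7% of the variance, from -6.47 for p38 1 to 47.03 for p38 4. The p38 minus LacZ difference itself, tested as an interaction in limma, was higher in Started than in Completed arrays for 266 probe sets and lower for 501. RNA integrity and array brightness could be causes, but the LacZ arrays with the lowest and highest β-actin 3′ to 5′ ratio (1.90 and 2.55) lay only 2.07 apart on the component, and the dimmest and brightest LacZ arrays 0.78 apart, against a span of 53.5 among p38 arrays. Those LacZ arrays say nothing of a trend among the 5 p38 arrays, where p38 4 and p38 5, highest on the component, had the lowest ratios (1.936 and 1.599) and p38 1, lowest on it, the lowest median signal (60.3), so both explanations stay open, as does the amount of delivered kinases each heart made, which was not tested. Fluidics status cannot be told apart from differences between the hearts, because Started holds a single LacZ array (median Started minus Completed difference of the changed probe sets, in the direction of change, -0.286 in p38 and 0.112 in LacZ).

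Fatty acid oxidation genes were lower while most contractile genes of the same cells were near their LacZ level in the main setting. This could reflect a smaller share of cardiomyocyte RNA, compressed signals of bright probe sets or the scaling. The medians of contractile and fatty acid oxidation genes were -0.008 and -0.369 there. With median centring they were -0.159 and -0.327, and with cyclic loess -0.086 and -0.326. With the signals as deposited they were -0.042 and -0.21, where all tested probe sets had 0.114. The contrast thus varied with scaling, and the comparisons by brightness used quantile-normalized values only. The test assumed that a smaller share would raise the markers of other cell types alike. Endothelial markers had a median of -0.14 (0.03 with the signals as deposited) where macrophage markers had 0.73 (permutation p = 0.005 over genes, which are not independent). These values go against an even rise. A share made smaller by added macrophage RNA would lower endothelial markers too, so they do not decide the question. The comparison of dimmer genes had 1 contractile gene below 13 and decided nothing (-0.133, permutation p = 0.581), and at the lower bound the fatty acid oxidation median of -0.195 against -0.008 met the rule written to exclude compression, yet it set 11 genes against 17 brighter ones (median 12.98 against 13.51), so it was left open. At 13 and above, fatty acid oxidation genes lay lower by a small margin (-0.121, exact permutation p = 0.0429 over 5 and 16 genes, which are not independent). The contractile genes there were still slightly brighter (median 13.56 against 13.46). This is a weak argument against compression as the whole account, since fold changes shrank with brightness across the 23 genes (Spearman's rho 0.71, permutation p = 0.00027). A smaller share of cardiomyocyte RNA, the scaling, compression of part of the pattern, a change in macrophage number and lower transcript levels in cardiomyocytes after p38 activation stay open.

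With the signals as deposited, most changed probe sets were higher in p38. The spike-in RNAs added at hybridisation, which do not come from the heart, were higher in p38 arrays by 0.244 on the log2 scale (exact permutation p = 0.0397, two-sided), more than the median shift of 0.114 of the tested probe sets. Brighter p38 arrays could be the source of that excess, but the spike-ins did not follow array brightness throughout. LacZ 1, with the highest median log2 signal of the LacZ arrays (6.534), had the lowest spike-in mean (8.981). Among p38 arrays the brightest, p38 5 (6.701), had the highest (9.689). The median log2 signal itself was higher in p38 arrays by 0.117 (exact permutation p = 0.222). The source of the excess stays open, and a true general rise of transcripts was not tested.

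Of 100 splits of the 10 arrays into 5 and 5, drawn with the real one included, 1 gave as many changed probe sets as the real split, itself, with 2979 against at most 7 in any other. With 100 splits the smallest possible share is 1 in 100. Every other split mixed LacZ and p38 arrays, so a true difference between the groups would add to the spread and lower those counts. The gap therefore does not measure how rare such a count would be by chance. For lists chance was not excluded, as 11 of the 100 splits shifted at least 16 lists and the highest other shifted 19. Every other split held unequal numbers of p38 arrays in its 2 parts and so kept some of the group difference. The list counts therefore do not measure chance either. The split with 19 set LacZ 1, LacZ 2, LacZ 4, LacZ 5 and p38 1 against the rest and changed 0 probe sets by limma. List by list, camera gave as small a p in 1 split for fatty acid oxidation, 2 for calcium handling and ion channels, 3 for antigen presentation and 4 for mitosis, each counting the real split, and in 5 or more for every other of the 27 lists tested in the comparison.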

How the results depend on the processing

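The arrays within each fluidics status were examined only after the data were seen, and all other alternatives were planned. With the signals as deposited, and the dimmest 40% chosen from those signals, 960 probe sets were higher and 87 lower, with median centring 776 were lower, with no filter on dim probe sets 867 were lower, and with array weights 2618 were higher and 2577 lower. Stricter thresholds gave 165 and 119 (adjusted p under 0.01) and 746 and 298 (at least 1.5-fold), as their construction requires. Within Completed arrays the counts were 2919 and 3364, within Started arrays, with 1 LacZ array, 3 and 2. Leaving out 1 array gave 693 to 2316 higher and 536 to 2149 lower. Apart from the stricter thresholds, the cause of these differences was not tested. Leaving out 1 array lowered the counts for some arrays and raised them for others, as without p38 1 (2316 and 2149). Camera with an estimated correlation left 0 lists higher and 0 lower, while the other choices made in advance gave 10 or 11 higher and 5 to 8 lower, against 12 and 5 within Completed and 4 and 5 within Started arrays. The mast cell list was also lost without p38 3 (adjusted p = 0.0674), with array weights (0.103) and with the replicate block (0.0502). The endothelial list was lost with the signals as deposited (adjusted p = 0.0796), and oxidative phosphorylation (0.0582) and extracellular matrix (0.178) with fry. Lists not called in the main setting were called in some others, T and NK cell markers higher in 4, neutrophil markers in 3 and heat shock genes in 1, beside those given in the report. Among lists with 1 member or none past the threshold, 2 neutrophil markers passed without LacZ 5 or p38 1, 2 mast cell markers without p38 1 or p38 3, 2 T and NK cell markers without p38 3, 2 atrial markers and 1 skeletal muscle marker without p38 1 and 1 B cell marker without p38 5. A pseudocount of 64 gave Il6 2.03-fold, Cbln2 3.16-fold, Ccna2 2.53-fold and Mmp12 1.86-fold, and Cbln2 was 2.82-fold higher with averaged probe sets and 4.62-fold without p38 5. The averaged probe sets of Myh6 reversed to -0.34 (adjusted p = 0.0176), which its second probe set accounts for by construction. Of 87 named genes past the threshold 50 kept their call in each setting they were run in, 60 with the signals as deposited, and 70 to 87 when 1 array was left out. A further 26 sign changes concerned results past the threshold in neither setting. The replicate block gave 1670 higher and 1410 lower and kept 85 of the 87 named genes, losing Lcn2 (adjusted p = 0.0529) and Cma1 (0.0593), but same-numbered samples shared only a number. Their deviations correlated at 0.08, 0.10, 0.04, -0.14 and 0.28, and not every sample correlated best with its own number. Signals near background limit dim genes.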

Other observations

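All lists in this part were written after the main table had been seen, from genes that stood out there, and each was tested on its other members only, whose values had not been looked at. The demand that under 5 of 100 splits give as small a p was added after the list tests had been seen, and it left the serine and clock lists open. Genes that break down branched-chain amino acids, prompted by a probe set of Aldh6a1, were lower, although the brightest probe set of Aldh6a1 did not pass (log2 fold change -0.27, adjusted p = 0.0521). Of 17 other members 7 fell and none rose, with a median log2 fold change of -0.347. The methylmalonyl-CoA mutase gene Mmut fell by 0.72 (adjusted p = 0.00818), Pcca by 0.40 and Bcat2, the mitochondrial branched-chain aminotransferase, by 0.40. Camera gave an adjusted p of 7.786e-07 over the 4 lists, an adjusted p = 0.199 with an estimated correlation, and as small a p in 3 of 100 splits of the arrays, which leaves a fall of the pathway as a hypothesis. The 4 lists were tested on quantile-normalized signals only. For the fatty acid oxidation list, 14 falls became 2 with the signals as deposited, 11 with median centring and 16 with cyclic loess. Genes of serine synthesis and amino acid uptake, many of them targets of the transcription factor ATF4, were prompted by Psat1 (at least 2.12-fold higher) and Atf4. Of 14 other members 7 rose and none fell (median 0.45), with asparagine synthetase (Asns) at 2.43-fold (adjusted p = 0.00774) and Mthfd2 at 2.28-fold.

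The circadian clock list, prompted by Usp2 and by probe sets of Nr1d2 other than its brightest (adjusted p = 0.0597), had 14 other members, of which Per2, Nr1d1, Hlf and Tef fell and none rose (median -0.499), while the clock activator gene Bmal1 had a log2 fold change of 0.41 (adjusted p = 0.0992). In the list of the plasminogen system and EGF receptor ligands, prompted by Plau (2.98-fold), its receptor Plaur (3.52-fold) and Hbegf (2.98-fold), 2 of 5 other members rose, Anxa2 and S100a10, with a median of 0.153. Camera gave these 3 lists adjusted p-values of 0.000827, 0.000906 and 0.0811, and 0.203, 0.121 and 0.199 as adjusted p with an estimated correlation. As small a p occurred in 13, 8 and 7 of the 100 splits, which kept some of the group difference. The plasminogen list was not shifted (median 0.153), and the shifts of the serine and clock lists could reflect structure among the arrays and stay open (medians 0.45 and -0.499). The hour at which each heart was taken is not given in the sources used here, and was not tested against the clock genes.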
